A study of Homo sapiens with 47 samples.

How the data were processed

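Messenger RNA was measured on 47 one-colour Agilent arrays from third-trimester human trophoblasts, the epithelial cells of the placenta. Per the labels, the cells of 4 placentas (numbered 1, 2, 4 and 5) were isolated enzymatically, purified on Percoll and plated under standard oxygen (20%). After 4 h, defined by the submitters as time 0, cultures stayed at standard oxygen or moved to hypoxia, and were harvested at 6, 12, 24, 48 and 72 h. The labels disagree on the hypoxic level: the series design gives 0% oxygen and the treatment protocol gives 1%, so the condition is called hypoxia below. The labels also give 2 arrays of placenta 1 at 8% oxygen (24 and 72 h) and second cultures of placenta 1 (1 array each at 0 h standard, 24 h hypoxic and 72 h hypoxic).

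Per the file headers, the scanned images were quantified with Agilent Feature Extraction 10.7.3.1 on a design annotated on hg19. The deposited array files hold the processed signal as an intensity, background-subtracted and detrended within each array and not normalized between arrays. They also hold, per the file headers, the unprocessed median intensity of each spot and of its local background. Spot flags (0 or 1, a kind of value other than a measurement) are deposited with them, per the file headers. The authors' value table holds an intensity on a linear scale, not centred per gene. Its normalization between arrays is not stated in the labels. Its values correlated with the log2 processed signal of the same array at 0.994 to 1.000 across probes, which are not independent replicates.

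The files gave between 47.9% and 61.0% of probes well above background per array, a 75th percentile of processed intensity between 124 and 433, and 0 saturated spots over all arrays. All scanner quality metrics were in range on 28 of the 47 arrays. The number of arrays limits the precision of every value below.

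The main values were log2 processed signals minus the log2 75th percentile of the array, after spots flagged as non-uniform or as population outliers were removed and replicate spots averaged. Levels below are on this log2 scale, with 0 at the 75th percentile of the array. Probes had to be well above background on at least 3 of the 42 main arrays. Gene symbols came from the RefSeq accession of each probe, matched without version to the supplied reference. Of 42405 distinct probes, 24910 had 1 symbol, 0 had several and 17495 had none. The 96 probes of Y-linked genes and of the XIST region were removed before any test. Each gene was represented by its probe with the highest mean, and probes without a symbol were kept under their own identity, which left 23628 tested genes and unnamed transcripts, 14676 of them with a symbol. The main matrix had 133 missing values.

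The placenta was the replicate. The main fit held the 42 first-culture arrays, without the second cultures and without the arrays at 8% oxygen, which have no replicates and are reported as values only. Groups at 6 h had 3 placentas, because placenta 5 has no arrays at that time, and all other main groups had 4. Comparisons were hypoxic minus standard at each of the 5 times, standard culture at 6, 24 and 72 h minus 0 h, hypoxia averaged over 12 to 72 h (the mean of each placenta, 4 against 4), and the interaction of time and hypoxia from 12 to 72 h. They were fitted with limma 3.58.1 in R 4.3.3, using its moderated test with a mean-variance trend, 2-sided. p-values were adjusted by Benjamini-Hochberg within each of the 10 comparisons, and genes under 0.05 were called. The 3 time comparisons share the 0 h arrays.

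Per the labels, hypoxic and standard cultures of a placenta come from the same donor, so a value with placenta as a block is given where it changes a call or moves a count by over 1.5 times. Deviations from the group mean correlated across genes at a median of 0.39 for the 19 pairs of hypoxic and standard arrays of a placenta, and at -0.12 for the 54 pairs of different placentas. Of those 19 pairs 18 exceeded 0.1, against 1 of the 54. The arrays lay on 6 slides scanned on 2 days. The arrays of placenta 1 filled their own slides and scan day, so that day cannot be told apart from placenta 1, while hypoxic and standard arrays occur on every slide. Differences within slides are given beside the pooled ones. They re-use arrays of the fit, and a slide with such pairs holds 1 to 3 of them, so they are no independent check.

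The 22 gene lists were written before the data were examined: hypoxia-inducible factor (HIF) targets, glycolysis, syncytiotrophoblast hormones and differentiation, antiangiogenic factors, cytotrophoblast, extravillous trophoblast, cell cycle, unfolded protein response, amino acid response and ATF4 targets, immediate early genes, heat shock, oxidative phosphorylation, cholesterol synthesis, lipid droplets and fatty acid handling, p53 targets, inflammatory cytokines and chemokines, interferon response, macrophages, fibroblasts and stroma, endothelium, blood cells, and decidua. Of their 494 genes 430 were measured. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the 22 lists of a comparison. Counts are given over all tested genes and adjusted over the list alone, and where a single count is given both were equal. A list that passed with the preset correlation also passed with the estimated one unless its estimated value is given. Camera has no fold rule.

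Named genes followed a rule also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls with the same sign in every placenta for averaged hypoxia and for 72 h of standard culture, and 4 of each for other comparisons. It adds the 6 smallest p-values of the interaction, up to 4 members per list with the smallest p, and always VEGFA, CA9, NDRG1, SLC2A1, ADM, CGA, CGB3, CYP19A1, ERVW-1, GCM1, HSD3B1, LEP, FLT1, KRT7, HLA-G and VIM. CA9 had no probe among the tested genes. Members outside the rule that complete a count of 5 or fewer were chosen after their values were seen.

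A gene that was not well above background on any array of a group was given a bound in place of a fold. The dim arrays were set to the lowest signal well above background on that array, and the gene is reported as at least that many times higher or lower where every array of the other group was above background. Other bounds are not printed. The bounds hold on the scale of the processed signal, and normexp correction, which adds an offset to every signal, gives such genes smaller differences. No fold is given where both groups were below background or the bound was under 1. Related genes (CGB copies and LHB, the PSG family, CSH genes and GH2, HSPA1A and HSPA1B, the HBG pair) share sequence, and binding to one another's probes was not measured.

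Calling was tested on simulated data with 100 genes shifted per size and normal noise at each gene's measured spread, independent between arrays. That may favour averaged hypoxia. At a log2 difference of 2, 100% were recovered for averaged hypoxia, 75% at 6 h and 82% to 85% at 12 to 72 h. Time comparisons recovered 73% to 80% and the interaction 65%. At 1 these were 68%, 36%, 36% to 39%, 33% to 38% and 13%, and 5 to 14 unshifted genes were called.

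Alternatives planned before the data were examined were quantile normalization, the authors' value table, no filter or a stricter filter on dim genes, the mean over a gene's probes, placenta or slide as a block, another choice of samples in the fit, second cultures averaged in, no mean-variance trend, a 2-fold rule, the estimated correlation, and each placenta left out. A normexp background correction had been planned on mean signals, which the files lack, so it was run on median signals. That and the fit without the 6 h arrays of placenta 2, whose negative controls lay apart from the rest, were chosen after seeing the data.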

Results

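The series holds 47 arrays of cultured primary trophoblasts from 4 placentas. Freshly plated trophoblasts fuse over days in culture into hormone-making syncytiotrophoblast, and the series follows that course with and without hypoxia. Standard oxygen is represented by 5 arrays at 0 h, 3 at 6 h and 4 each at 12, 24, 48 and 72 h. Hypoxia is represented by 3 arrays at 6 h, 4 at 12 h, 5 at 24 h, 4 at 48 h and 5 at 72 h, and 8% oxygen by 1 array at 24 h and 1 at 72 h. Second cultures of placenta 1 are included. Between 47.9% and 61.0% of probes were well above background per array, with main group means from 51.6% at 0 h to 56.5% at 6 h of standard culture. Depth is an array's intensity (75th percentile 124 to 433). The 8% array at 72 h was lowest in both.

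The first question was which genes differ between hypoxic and standard culture over 12 to 72 h, with each placenta averaged over the 4 times (n = 4 placentas per condition). Targets of the oxygen-sensing factor HIF (28 of 32) and glycolysis genes (16 of 20) were higher in hypoxic trophoblasts. In the unfolded protein response 13 of 18 were higher (adjusted p = 0.4 with an estimated correlation). Among lower genes were 23 of 34 of syncytiotrophoblast, 11 of 16 of heat shock, 16 of 39 of oxidative phosphorylation and 10 of 24 of cholesterol synthesis. Those lists had an adjusted p = 0.083, 0.33, 0.4 and 0.61 with an estimated correlation, in that order. Of 23628 genes 7026 passed limma's moderated test, 3775 higher and 3251 lower under hypoxia, and 6977 of them had the same sign in every placenta. Of the called genes 3335 differed by at least 2-fold, and 9299 had an unadjusted p under 0.05. The count was 4254 without placenta 4 and 3944 without placenta 2. On the 6 slides, between 91.8% and 99.6% of the called genes had the pooled sign within the slide. A slide held 1 to 3 pairs and only some of the 4 times, so ranges over slides mix times and placentas with slides. The lowest share came from a slide with a single pair, placenta 1 at 72 h.

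HIF, which low oxygen stabilises, had targets that formed the list with the smallest p, and 28 of 32 rose while 2 fell. HILPDA, a lipid droplet protein, rose by 4.27 ± 0.13 (log2, SE) with an adjusted p of 1.6e-07, and NDRG1 by 3.66 ± 0.11 (adjusted p = 1.6e-07), both in 4 of 4 placentas. The mitochondrial adenylate kinase AK4 rose by 4.70, the oxidase ERO1A by 4.30, VEGFA by 2.40 ± 0.25 and the glucose transporter SLC2A1 by 1.46 ± 0.12. The targets that fell were ANGPTL4 (-1.95, adjusted p = 0.00036) and SERPINE1 (-2.91, adjusted p = 0.00012). ADM differed by 0.29 ± 0.14 (adjusted p = 0.15, 3 of 4 placentas). The median of the list was 2.13 (adjusted p = 2.5e-20, and adjusted p = 0.00076 with an estimated correlation), and 28 rose and 2 fell when adjusted over the list alone. Within slides its median lay between 1.81 and 2.52, the lowest from the single pair of placenta 1 at 72 h. Glycolysis genes had 16 of 20 higher and 1 lower (SLC16A3, -0.76), the same counts adjusted over the list alone, with a median of 1.88 (adjusted p = 1.8e-12). HK2 rose by 4.73 ± 0.15, LDHA by 3.88 and PFKFB3, which makes fructose 2,6-bisphosphate, by 5.13 with 1 of 16 standard arrays above background and 1.88 with normexp correction.

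Syncytiotrophoblast genes fell, 23 of 34 with none higher, and 25 lower with 1 higher when adjusted over the list alone. The median was -2.70 (adjusted p = 2.3e-17, adjusted p = 0.083 with an estimated correlation), and -4.0 to -1.28 within slides. CGB3, a subunit of chorionic gonadotropin, fell by 5.59 ± 0.38 (adjusted p = 6.6e-06) and was above background on 15 of 16 hypoxic arrays. The common subunit CGA fell by 3.93 ± 0.36 (adjusted p = 4.7e-05), the transcription factor GCM1 by 3.64, aromatase (CYP19A1) by 3.38 ± 0.18 and PGF by 3.38. HSD3B1, of progesterone synthesis, fell by 3.01 ± 0.21 and the fusion protein ERVW-1 by 1.64 ± 0.26 (adjusted p = 0.001), all in 4 of 4 placentas. Placental galectins and pregnancy-specific glycoproteins supplied most of the 10 largest falls: LGALS13 (-5.89 ± 0.46), LGALS14 (-5.37), PSG3 (-4.82), PSG1 (-4.56), PSG5 (-4.35), PSG8 (-4.34) and PSG2 (-4.33). HOPX (-4.68) and TREML2 (-4.91, or -2.25 with normexp correction, 3 of 16 hypoxic arrays above background) completed them with CGB3. Among markers of other trophoblasts, cytotrophoblast genes had 4 of 24 higher (CDH1, FGFR2, MET, NRP2) and 7 lower, with a median of -0.17 (adjusted p = 0.56) and 4 higher and 8 lower adjusted over the list alone. Extravillous trophoblast genes had 5 of 19 higher (ASCL2, FSTL3, MMP11, MYCN, PLAC8) and 5 lower (CCR1, DIO2, HPGD, LAIR2, TAC3), with 6 and 7 adjusted over the list alone and a median of -0.17 (adjusted p = 0.85). KRT7 fell by 0.86 ± 0.25 (adjusted p = 0.027), with an adjusted p of 0.14 without placenta 2 and 0.13 without placenta 4. HLA-G differed by 0.30 (adjusted p = 0.54).

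Genes of the unfolded protein response rose, 13 of 18 with none lower, at a median of 1.21 (adjusted p = 6.9e-07, adjusted p = 0.4 with an estimated correlation). The chaperones HSPA5 (2.83 ± 0.36) and HSP90B1 (2.00) and the disulfide isomerase PDIA4 (2.82 ± 0.25) were among them. The within-slide medians ran from -0.42 to 1.74, the lowest from the single pair of placenta 1 at 72 h. Amino acid response genes had 8 of 19 higher and none lower, with 8 and 1 adjusted over the list alone. Their median was 0.41 (adjusted p = 0.018, adjusted p = 0.52 with an estimated correlation), with an adjusted p of 0.066 without placenta 2. Within slides it ran from -0.19, again from that single pair, to 0.75. Heat shock genes had 11 of 16 lower and none higher, with 13 lower and 1 higher adjusted over the list alone and a median of -0.70 (adjusted p = 2.8e-05, adjusted p = 0.33 with an estimated correlation). HSPB1 fell by 3.96 ± 0.17 and HSPA8 by 2.21. Oxidative phosphorylation genes had 16 of 39 lower and 1 higher (SDHA, 0.36), with 20 and 1 adjusted over the list alone. Their median was -0.33 (adjusted p = 4.7e-06, adjusted p = 0.4 with an estimated correlation), and ATP5F1B fell by 0.78. Cholesterol synthesis genes had 10 of 24 lower and 1 higher (SC5D, 1.25), with 12 and 1 adjusted over the list alone. Their median was -0.54 (adjusted p = 0.00071, adjusted p = 0.61 with an estimated correlation), with INSIG1 at -1.37 and LDLR at -1.49. Targets of p53 had 9 of 20 higher and 2 lower (GDF15, -1.59, and PMAIP1, -1.30), with a median of 0.38 (adjusted p = 0.038, adjusted p = 0.4 with an estimated correlation). Their adjusted p was 0.099 without placenta 1 and 0.06 without placenta 2.

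The remaining lists did not pass the test. Antiangiogenic factors had 4 of 9 higher (HTRA1, IGFBP3, INHBA, SERPINF1) and 1 lower (ENG), with a median of 0.35 (adjusted p = 0.12). IGFBP3 rose by 4.44 ± 0.28 and FLT1 differed by -0.05 ± 0.49 (adjusted p = 0.96). Immediate early genes had 6 of 22 higher and 6 lower (median -0.23, adjusted p = 0.67), among them FOS at 1.67 and JUNB at -2.26. Lipid droplet genes had 5 of 20 higher (ACSL1, AGPAT2, FABP5, PLIN2, SCD) and 8 lower, with 7 and 8 adjusted over the list alone and a median of -0.17 (adjusted p = 0.67). Cell cycle genes had 4 of 32 higher (CCNE2, MCM3, TTK, TYMS) and 5 lower (AURKB, CCNB1, KIF20A, TOP2A, TPX2), with a median of 0.10 (adjusted p = 0.93). In the inflammatory list LIF rose (6 of 16 standard arrays above background) and CXCL5 fell (-0.82) of 16. Its median was -0.09, its mean 0.04 and the direction of its test down (adjusted p = 0.84). In the interferon list STAT1 fell (-1.35) of 20. Its median was 0.00, its mean -0.02 and its test down (adjusted p = 0.84).

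Among markers of other cells, the macrophage list had 1 of 11 higher (CD68) and 3 lower (CD163, CSF1R, FCER1G) at a median of -0.03 (adjusted p = 0.61). The fibroblast list had 4 of 11 higher (ACTA2, COL1A1, PDGFRB, VIM) and 1 lower (POSTN), with 4 and 2 adjusted over the list alone and a median of 0.04 (adjusted p = 0.69). VIM was called higher (adjusted p = 0.00048) with 8 of 16 hypoxic and no standard arrays above background, and its adjusted p was 0.35 with normexp background correction. The endothelium list had TEK higher and CDH5 lower of 5, with a median of -0.11, a mean of 0.53 and its test up (adjusted p = 0.93). The blood cell list had 2 of 14 lower (S100A9, SLC4A1) and none adjusted over the list alone, at a median of -0.11 (adjusted p = 0.45). The decidua list had 2 of 5 higher (IGFBP1 and WT1) at a median of 0.71 (adjusted p = 0.44). With genes below background on every array of a group set to their bounds, the medians of lists that passed in any comparison moved by at most 0.37.

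The largest rises under averaged hypoxia came from genes that were near background in standard culture. SLC30A10, a manganese exporter, rose by 6.31 ± 0.42 (adjusted p = 6.3e-06), with 2 of 16 standard arrays above background. The kinase PNCK was at least 38.4-fold higher, and FGD5 at least 28.3-fold, and VSTM2L was called higher with 15 of 16 hypoxic and no standard arrays above background. CALHM6 rose by 5.97 ± 0.25 (9 of 16 standard arrays), RIMKLA by 5.09 (8 of 16) and ZNF300P1 by 5.19 (1 of 16). The angiopoietin receptor TEK rose by 5.71 ± 0.49 (2 of 16) and EGLN3, a hydroxylase that marks HIF for degradation, by 5.23 ± 0.29 (2 of 16). All these genes rose in 4 of 4 placentas. Against so dim a group the size of a rise depends on the background correction: with normexp all were called at smaller log2 differences, among them TEK at 2.54, FGD5 at 2.29, PNCK at 2.37, SLC30A10 at 2.72, EGLN3 at 2.27, ZNF300P1 at 2.20, RIMKLA at 3.01, CALHM6 at 3.69 and VSTM2L at 1.65. LEP differed by 1.36 ± 0.47 (adjusted p = 0.054, 9 of 16 hypoxic and 2 of 16 standard arrays above background) and passed with placenta as a block (adjusted p = 0.016) and without placenta 4 (0.03).

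**Figure D1:**
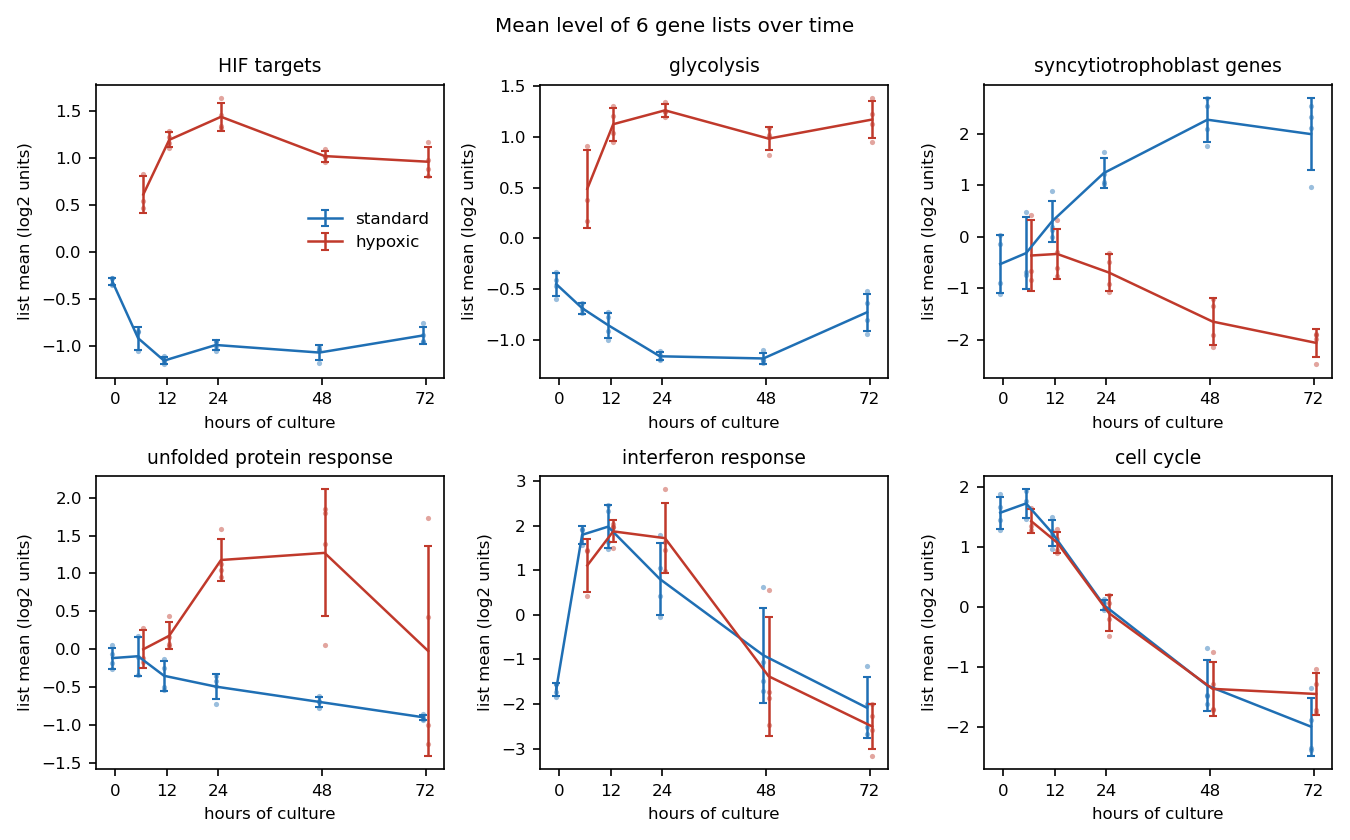
Mean log2 level of 6 gene lists (vertical axis, each gene centred on its mean over the main arrays) against hours of culture. Points are placentas and lines group means with bars of 1 SD, standard culture in blue and hypoxia in red. HIF targets and glycolysis genes were higher under hypoxia from 6 h, and syncytiotrophoblast genes lay lower under hypoxia at 72 h, by a median over the members (not the plotted mean) of 3.76.

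After 6 h (n = 3 placentas per condition) the question was which genes respond first. Of the HIF targets 20 of 32 were higher and of the glycolysis genes 9 of 20, and 0 of 34 syncytiotrophoblast genes were called. The test called 373 genes, most of them in none of the lists, 250 higher and 123 lower, each with the same sign in 3 of 3 placentas, and 270 of them differed by at least 2-fold. With placenta as a block 936 were called, and 63 when only the 6 h arrays entered the fit. The count fell to 138 without placenta 1, 96 without placenta 2 and 123 without placenta 4. The share of called genes that were higher was 67.0%, and 51.1% after quantile normalization and 50.5% with the block. Without the 6 h arrays of placenta 2, a check chosen after seeing the data, 137 genes were called (127 higher, 10 lower). The called genes had the pooled sign in 100% of cases on the 3 slides that hold both conditions. Each of these slides holds 1 of the 3 placentas, so this restates the 3 of 3 placentas.

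HIF targets had 20 of 32 higher and none lower at 6 h, and 22 adjusted over the list alone. Their median was 1.46 (adjusted p = 1.9e-53), within slides 1.22 to 1.82. HILPDA rose by 4.75 ± 0.25 (adjusted p = 4.8e-16), BNIP3 by 2.46, AK4 by 2.58, NDRG1 by 2.30 ± 0.21 and SLC2A1 by 1.65 ± 0.18. ADM rose by 0.93 ± 0.25 (adjusted p = 0.044). The adjusted p of ADM was 0.12 without placenta 1, 0.43 without placenta 2 and 0.34 without placenta 4. VEGFA differed by 0.94 ± 0.40 (adjusted p = 0.33). Glycolysis genes had 9 of 20 higher, 13 adjusted over the list alone, at a median of 0.81 (adjusted p = 4.9e-20), with PDK1 at 3.32 and HK2 at 2.43. The lipid droplet coat protein PLIN2 rose by 3.22 ± 0.27 (adjusted p = 2.6e-10). The largest rises were SLC30A10 (at least 40.8-fold), HILPDA, GPR146 (4.60, 1 of 3 standard arrays above background) and ZNF300P1 (at least 20.3-fold). With normexp correction SLC30A10 rose by 2.32, ZNF300P1 by 2.22 and GPR146 by 2.04. GPR146 had an adjusted p of 0.11 when only the 6 h arrays entered the fit.

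The largest falls at 6 h were SECTM1 (-2.45, 1 of 3 hypoxic arrays above background), WNT5A (-2.11), SPSB2 (-1.89, adjusted p = 7.6e-07) and UBTF (-1.84, 2 of 3 hypoxic arrays), each in 3 of 3 placentas. With normexp correction SECTM1 differed by -0.77 (adjusted p = 0.21), UBTF by -0.42 (0.44) and WNT5A had an adjusted p of 0.051. The adjusted p of SECTM1 was 0.013, and 0.054, 0.2 and 0.18 without placenta 1, 2 or 4. For WNT5A it was 0.014, and 0.17, 0.4 and 0.097 without them, and for UBTF it was 0.0086, and 0.38 without placenta 2 and 0.17 without placenta 4. Antiangiogenic factors passed at a median of 0.53 (adjusted p = 0.01, adjusted p = 0.17 with an estimated correlation), with IGFBP3 higher (2.30), 2 higher adjusted over the list alone, and an adjusted p of 0.091 without placenta 1. Cell cycle genes lay at -0.26 (adjusted p = 0.0033, adjusted p = 0.69 with an estimated correlation, and 0.075 after quantile normalization) with none called. Oxidative phosphorylation genes lay at -0.18 with none called (adjusted p = 0.00041, adjusted p = 0.6 with an estimated correlation). Interferon genes lay at -0.65 with none called (adjusted p = 0.0029, adjusted p = 0.69 with an estimated correlation, and 0.069 without placenta 2). Cholesterol genes lay at -0.21 with none called (adjusted p = 0.022, adjusted p = 0.69 with an estimated correlation). For cholesterol genes it was 0.19 after quantile normalization, 0.15 in the authors' table, 0.082 without placenta 1 and 0.069 without placenta 2. Immediate early genes lay at 0.59 (adjusted p = 0.039, adjusted p = 0.69 with an estimated correlation), with FOS higher (1.18) and BTG2 lower (-0.90), 2 and 1 adjusted over the list alone, and an adjusted p of 0.096 without placenta 1 or without placenta 4 and 0.25 with normexp correction. Syncytiotrophoblast genes had a median of -0.03 with none called (adjusted p = 0.36), CGA at 0.02 and CGB3 at -0.03. Inflammatory genes (0.51, adjusted p = 0.093) passed with placenta as a block (0.035).

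At 12 h (n = 4 placentas per condition) 26 of 32 HIF targets and 16 of 20 glycolysis genes rose, and 10 of 34 syncytiotrophoblast genes fell (adjusted p = 0.44 with an estimated correlation). The test called 3438 genes, 1703 higher and 1735 lower, 3357 with the same sign in every placenta and 1743 of at least 2-fold. With placenta as a block 5284 were called. Without placenta 2 the count was 1849, without placenta 4 it was 1877 and without placenta 5 it was 2069. Within the 3 slides holding both conditions, 98.7% to 99.9% of the called genes had the pooled sign. HIF targets had 26 of 32 higher and 1 lower (SERPINE1, -1.42), 28 and 1 adjusted over the list alone, at a median of 2.36 (adjusted p = 4.2e-53). NDRG1 rose by 4.74 ± 0.18 (adjusted p = 9.3e-21), HILPDA by 4.82 ± 0.22, SLC2A1 by 2.54, ADM by 1.22 ± 0.22 and VEGFA by 1.75 ± 0.35 (adjusted p = 0.00045). Glycolysis genes had 16 of 20 higher and none lower, 16 and 1 adjusted over the list alone, at a median of 1.44 (adjusted p = 1.5e-25).

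Syncytiotrophoblast genes at 12 h had 10 of 34 lower and none higher, 12 adjusted over the list alone, at a median of -0.59 (adjusted p = 0.00013, adjusted p = 0.44 with an estimated correlation). PGF fell by 2.53 ± 0.26, GCM1 by 1.96 ± 0.37, PSG1 by 1.69 and HSD17B1 by 1.39, in 4 of 4 placentas each. HSD3B1 fell by 0.98 ± 0.33 (adjusted p = 0.04). Its adjusted p was 0.17, 0.14, 0.053 and 0.078 without placenta 1, 2, 4 or 5. CGA (-0.60, adjusted p = 0.48) and CGB3 (-0.51, adjusted p = 0.62) were not called, nor was ERVW-1 (-0.82, adjusted p = 0.075), which passed with placenta as a block (0.0043) and without placenta 1 (0.0094). Cholesterol synthesis genes had 9 of 24 lower at a median of -0.66 (adjusted p = 1.3e-05, adjusted p = 0.49 with an estimated correlation), and oxidative phosphorylation genes 6 of 39 lower at -0.27 (adjusted p = 0.00029, adjusted p = 0.44 with an estimated correlation). Immediate early genes had 8 of 22 higher and 3 lower (BTG2, IER2, JUNB), 12 and 3 adjusted over the list alone, with FOS at 2.55 and a median of 0.78 (adjusted p = 0.0024). The immediate early list had an adjusted p = 0.5 with an estimated correlation and 0.073 without placenta 5. Antiangiogenic factors had 4 of 9 higher (IGFBP3, INHBA, HTRA1, SERPINF1) at a median of 0.49 (adjusted p = 0.00036). The unfolded protein response had HERPUD1 (1.62) and HSPA5 (1.68) higher of 18 at a median of 0.39 (adjusted p = 0.023, adjusted p = 0.66 with an estimated correlation). Its adjusted p was 0.28 with normexp correction and 0.063 in the authors' table. With placenta as a block inflammatory (0.74, adjusted p = 0.055), amino acid response (0.39, 0.055) and extravillous genes (0.46, 0.064) passed as lists, at 0.024, 0.038 and 0.038. The largest rises were SLC30A10 (at least 36.7-fold), ZNF300P1 (at least 51.2-fold), TEK (at least 50.3-fold) and RIMKLA (at least 41.8-fold). The largest falls were TCHHL1 (-3.70, 3 of 4 hypoxic arrays above background), GDPD1 (at least 6.48-fold lower), SLC30A2 (-3.47) and ABCC3 (at least 6.56-fold lower). With normexp correction SLC30A10 rose by 2.63, ZNF300P1 by 2.96, TEK by 2.78 and RIMKLA by 2.59, TCHHL1 fell by 1.99, and GDPD1 (-0.69, adjusted p = 0.055) and ABCC3 (-0.59, adjusted p = 0.1) were not called.

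At 24 h (n = 4 placentas per condition) 22 of 34 syncytiotrophoblast genes were lower under hypoxia (adjusted p = 0.055 with an estimated correlation). Of the unfolded protein response genes 14 of 18 were higher (adjusted p = 0.26 with an estimated correlation). The test called 6398 genes, 3225 higher and 3173 lower, 6209 with the same sign in every placenta and 3619 of at least 2-fold. Within the 4 slides holding both conditions, 98.8% to 99.9% of them had the pooled sign. Syncytiotrophoblast genes had 22 of 34 lower and none higher, 22 and 2 adjusted over the list alone, at a median of -2.21 (adjusted p = 8.2e-13, adjusted p = 0.055 with an estimated correlation). CGB3 fell by 3.67 ± 0.52 (adjusted p = 9.9e-07), CGA by 3.05 ± 0.47, HSD3B1 by 2.58 ± 0.33 and CYP19A1 by 2.24 ± 0.36, each in 4 of 4 placentas. The largest falls were LGALS14 (-6.23), PAQR9 (at least 28.8-fold), LGALS13 (-5.71) and HMGCS2 (at least 18.7-fold). The largest rises were PNCK (at least 47.5-fold), IGFBP3 (6.48 ± 0.40), SLC30A10 (6.42, 1 of 4 standard arrays above background) and CALHM6 (at least 57.6-fold). With normexp correction PNCK rose by 2.60, SLC30A10 by 2.90 and CALHM6 by 2.98, while PAQR9 fell by 2.20, HMGCS2 by 1.74 and CGB3 by 2.23.

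HIF targets at 24 h had 28 of 32 higher and 2 lower (ANGPTL4, -1.89, and SERPINE1, -2.75) at a median of 2.22 (adjusted p = 5.4e-33), with VEGFA at 2.26 ± 0.35 and ADM at 1.03 ± 0.22. Glycolysis genes had 16 of 20 higher and 1 lower (PFKM, -0.76) at a median of 2.34 (adjusted p = 2.1e-20). The unfolded protein response had 14 of 18 higher and none lower, 16 adjusted over the list alone, at a median of 1.63 (adjusted p = 4.3e-08, adjusted p = 0.26 with an estimated correlation), with HSPA5 at 3.36 ± 0.56. Amino acid response genes had 9 of 19 higher and none lower, 10 adjusted over the list alone, at a median of 0.76 (adjusted p = 0.001, adjusted p = 0.26 with an estimated correlation). Oxidative phosphorylation genes had 25 of 39 lower and 1 higher (SDHA, 0.70), 26 and 1 adjusted over the list alone, at a median of -0.58 (adjusted p = 6.7e-10, adjusted p = 0.08 with an estimated correlation). Targets of p53 had 10 of 20 higher and 2 lower (GDF15, -0.92, and PMAIP1, -1.17), 10 and 3 adjusted over the list alone, at a median of 0.43 (adjusted p = 0.0031, adjusted p = 0.095 with an estimated correlation). Antiangiogenic factors had 3 of 9 higher (IGFBP3, INHBA, HTRA1), 3 and 1 lower adjusted over the list alone, at a median of 0.94 (adjusted p = 0.0088, adjusted p = 0.095 with an estimated correlation). Cholesterol genes had 8 lower and 1 higher (SC5D, 1.22), 11 and 1 adjusted over the list alone, at a median of -0.79 (adjusted p = 0.0031, adjusted p = 0.73 with an estimated correlation). The adjusted p of the cholesterol list was 0.12 without placenta 5, and its within-slide medians ran from -1.41 to 0.09. In the heat shock list 6 of 16 fell and 2 rose (HSPA4L, 0.71, and HSPA6, 1.95) at a median of -0.16 and a mean of -0.54 (adjusted p = 0.032, adjusted p = 0.64 with an estimated correlation). The heat shock list had within-slide medians from -0.67 to 0.15 and an adjusted p of 0.053 with placenta as a block, 0.084 with normexp correction, 0.077 without placenta 1 and 0.067 without placenta 2. In the interferon list IFIH1, OAS2, RSAD2 and USP18 rose of 20, at a median of 1.00 (adjusted p = 0.049, adjusted p = 0.85 with an estimated correlation). That list had an adjusted p of 0.16 without placenta 2 and 0.7 with the second cultures averaged in. FLT1 (1.28, adjusted p = 0.11) and LEP (adjusted p = 0.06, 2 of 4 hypoxic and no standard arrays above background) passed with placenta as a block, at 0.036 and 0.016. FLT1 was higher in 3 of 4 placentas, and differed by 0.49 without placenta 1 (adjusted p = 0.46) and by 1.81 without placenta 5 (0.04). LEP had an adjusted p of 0.035 without placenta 4 and 0.69 with normexp correction.

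At 48 h (n = 4 placentas per condition) the count of genes was the highest of the 5 times, and CGB3 and LGALS13 fell the furthest. The test called 8753 genes, 4715 higher and 4038 lower, 8292 with the same sign in every placenta and 5453 of at least 2-fold. Within the 2 slides holding both conditions, 97.2% to 99.3% of them had the pooled sign. Syncytiotrophoblast genes had 26 of 34 lower and none higher, 30 adjusted over the list alone, at a median of -4.01 (adjusted p = 2.8e-22, and adjusted p = 0.0039 with an estimated correlation). CGB3 fell by 9.16 ± 0.52 (adjusted p = 2.3e-16), LGALS13 by 8.41, LGALS14 by 7.34 and LHB by 6.85, and HOPX by 6.73, each in 4 of 4 placentas. CGA fell by 5.63 ± 0.47, GCM1 by 5.33 and CYP19A1 by 4.97. The largest rises were LHFPL6 (7.01, 3 of 4 standard arrays above background), CALHM6 (6.85, 3 of 4), PNCK (at least 55.5-fold) and TLCD3A (6.57, 2 of 4). With normexp correction PNCK rose by 2.81 and TLCD3A by 3.89.

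HIF targets at 48 h had 27 of 32 higher and 2 lower (ANGPTL4 and SERPINE1), 28 and 3 adjusted over the list alone, at a median of 1.93 (adjusted p = 3e-18), with VEGFA at 2.97 ± 0.35. SLC2A1 rose by 0.48 ± 0.16 (adjusted p = 0.014), with 0.068 without placenta 1 and 0.072 without placenta 4. ADM differed by -0.48 (adjusted p = 0.081) and passed with placenta as a block (0.046), after quantile normalization (0.028) and without placenta 5 (0.02). Glycolysis genes had 15 of 20 higher and 1 lower (SLC16A3, -2.12) at a median of 1.99 (adjusted p = 1.2e-11). The unfolded protein response had 14 of 18 higher and none lower, 15 adjusted over the list alone, at a median of 1.76 (adjusted p = 9e-07, adjusted p = 0.37 with an estimated correlation), and PDIA4 rose by 4.53 ± 0.39. Of the heat shock genes 12 of 16 fell and none rose, 13 adjusted over the list alone, at a median of -1.40 (adjusted p = 1.8e-08, adjusted p = 0.053 with an estimated correlation), with HSPB1 at -5.49 ± 0.34. Oxidative phosphorylation genes had 19 of 39 lower at a median of -0.33 (adjusted p = 4.2e-05, adjusted p = 0.32 with an estimated correlation). Targets of p53 had 11 of 20 higher and 2 lower at a median of 0.82 (adjusted p = 0.016, adjusted p = 0.22 with an estimated correlation), with DDB2 at 2.95 and falls of GDF15 (-2.61) and PMAIP1 (-1.82). Amino acid response genes had 8 of 19 higher and 1 lower (CEBPB, -0.78) at a median of 0.75 (adjusted p = 0.0096, adjusted p = 0.45 with an estimated correlation). KRT7 fell by 1.25 (adjusted p = 0.0047, 0.089 without placenta 4), and VIM was at least 2.32-fold higher (adjusted p = 0.00013), but was not called with normexp correction (0.25, adjusted p = 0.52). HLA-G (0.74, adjusted p = 0.12) passed with placenta as a block (0.00021) and without placenta 4 (0.022), and FLT1 (-0.90, adjusted p = 0.25) passed without placenta 1 (0.0074).

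At 72 h (n = 4 placentas per condition) 30 of 34 syncytiotrophoblast and 13 of 16 heat shock genes were lower in hypoxic trophoblasts, and 25 of 32 HIF targets were higher. The test called 7420 genes, 3986 higher and 3434 lower, 6825 with the same sign in every placenta and 4414 of at least 2-fold. Within the 4 slides holding both conditions, 96.1% to 99.4% of them had the pooled sign. Syncytiotrophoblast genes had 30 of 34 lower and none higher, 30 and 1 adjusted over the list alone, at a median of -3.76 (adjusted p = 6.9e-28, and adjusted p = 0.0011 with an estimated correlation), within slides -4.97 to -3.17. CGB3 fell by 9.02 ± 0.52 (adjusted p = 7.5e-16, 3 of 4 hypoxic arrays above background), LGALS13 by 8.14, PSG3 by 7.52, LHB by 6.68, CGA by 6.43 ± 0.47 and CYP19A1 by 5.71 ± 0.36, each in 4 of 4 placentas. The largest rises were FGD5 (at least 74.3-fold), CALHM6 (6.75), PNCK (at least 50.5-fold) and the kisspeptin receptor KISS1R (at least 28.2-fold). With normexp correction FGD5 rose by 3.07, PNCK by 2.44 and KISS1R by 1.88.

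HIF targets at 72 h had 25 of 32 higher and 3 lower (ADM, ANGPTL4 and SERPINE1), 26 and 3 adjusted over the list alone, at a median of 1.78 (adjusted p = 4.4e-19). ADM fell by 0.62 ± 0.22 (adjusted p = 0.025, 0.24 without placenta 1 and 0.15 without placenta 2), while VEGFA rose by 2.62 ± 0.35 and SLC2A1 by 0.84 ± 0.16. Glycolysis genes had 15 of 20 higher and 1 lower (SLC16A3, -1.24) at a median of 1.67 (adjusted p = 1.1e-12). Heat shock genes had 13 of 16 lower and none higher, 13 and 1 adjusted over the list alone, at a median of -1.22 (adjusted p = 6.4e-09, and adjusted p = 0.043 with an estimated correlation), with HSPA1A at -4.44 ± 0.57. Immediate early genes had 11 of 22 lower and 3 higher (FOS, JUN, NR4A2) at a median of -0.77 (adjusted p = 0.0012, adjusted p = 0.65 with an estimated correlation), with JUNB at -3.16. Cell cycle genes had 12 of 32 higher and none lower, 13 adjusted over the list alone, at a median of 0.50 (adjusted p = 0.031, adjusted p = 0.65 with an estimated correlation). TYMS rose by 1.27 ± 0.26. The cell cycle list had an adjusted p of 0.19 without placenta 1, 0.19 with normexp correction (median 0.12), 0.072 after quantile normalization and 0.073 with the second cultures averaged in. The unfolded protein response was not called (median 0.84, adjusted p = 0.054, within slides -0.42 to 2.64), with 8 of 18 higher and 2 lower (EDEM1, XBP1) and PDIA4 at 3.77. It passed with placenta as a block (0.048), as did inflammatory (-0.99, adjusted p = 0.058) and extravillous genes (-1.26, 0.088), at 0.014 and 0.034. FLT1 fell by 1.54 ± 0.58 in 3 of 4 placentas (adjusted p = 0.041). Its adjusted p was 0.23, 0.12 and 0.25 without placenta 2, 4 or 5, and 0.064 with normexp correction. KRT7 fell by 1.32 (adjusted p = 0.0038, 0.13 without placenta 2 and 0.053 without placenta 4), and VIM was at least 6.40-fold higher, or by a log2 difference of 0.71 with normexp correction.

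The next question was whether the difference between hypoxic and standard culture itself changed from 12 to 72 h, tested as an interaction (n = 4 placentas per group). Of 34 syncytiotrophoblast genes 25 passed, each with a lower difference at 72 h than at 12 h, and of 32 HIF targets 17 passed, 12 with a lower and 5 with a higher difference at 72 h. The interaction called 4652 genes, 3803 of them with a change of at least 2-fold between times. With placenta as a block 7602 were called, and 2175 without placenta 2 and 2047 without placenta 4. The 6 smallest p-values belonged to TBX3, LHB, CGB3, PGRMC2, SPIRE2 and INSL4. CGB3 differed by -0.51, -3.67, -9.16 and -9.02 at 12, 24, 48 and 72 h (adjusted p = 7.4e-11), and INSL4 by 0.21, -1.65, -5.30 and -5.01. The transcription factor TBX3 differed by 0.25, -1.08, -2.97 and -3.38 (adjusted p = 4.1e-12), and PGRMC2 by 0.85, -0.27, -1.70 and -1.62. SPIRE2 differed by -0.90, -3.50, -4.57 and -4.07, and LHB by -0.20, -1.81, -6.85 and -6.68. Of the syncytiotrophoblast list 26 genes passed when adjusted over the list alone.

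Of the HIF targets 20 passed the interaction when adjusted over the list alone. SLC2A1 differed by 2.54, 2.00, 0.48 and 0.84 (adjusted p = 1.8e-08), NDRG1 by 4.74, 3.97, 3.21 and 2.72 (adjusted p = 1.5e-06), and ADM by 1.22, 1.03, -0.48 and -0.62 (adjusted p = 6.2e-06). VEGFA was not called (adjusted p = 0.27), nor was TEK (adjusted p = 0.84), which differed by at least 27.3-fold at 72 h. Heat shock genes passed in 12 of 16 cases, 13 adjusted over the list alone, and HSPA1A moved from 1.19 at 12 h to -4.44 at 72 h (adjusted p = 5.6e-07). Immediate early genes passed in 12 of 22 cases (14 adjusted over the list alone), p53 targets in 10 of 20 (13) and oxidative phosphorylation genes in 10 of 39. PDIA4 grew from 0.24 at 12 h to 4.53 at 48 h and 3.77 at 72 h (adjusted p = 2.2e-06). FLT1 passed with an adjusted p of 0.02, and 0.17, 0.16 and 0.057 without placenta 2, 4 or 5. VIM passed (adjusted p = 0.00025) and had 0.2 with normexp correction. KRT7 (0.33), LEP (0.92), ERVW-1 (0.11) and HLA-G (0.7) were not called, and with placenta as a block ERVW-1 (0.0042) and HLA-G (0.027) were. Across times, 149 genes were higher and 34 lower at all 5, and 720 higher and 642 lower at all 4 from 12 h on. At 48 and 72 h, 3133 higher and 2669 lower genes were shared against 795 and 587 expected, and 8 had opposite signs. At 12 and 72 h, 833 higher and 726 lower were shared against 287 and 252 expected, and 279 had opposite signs.

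**Figure D2:**
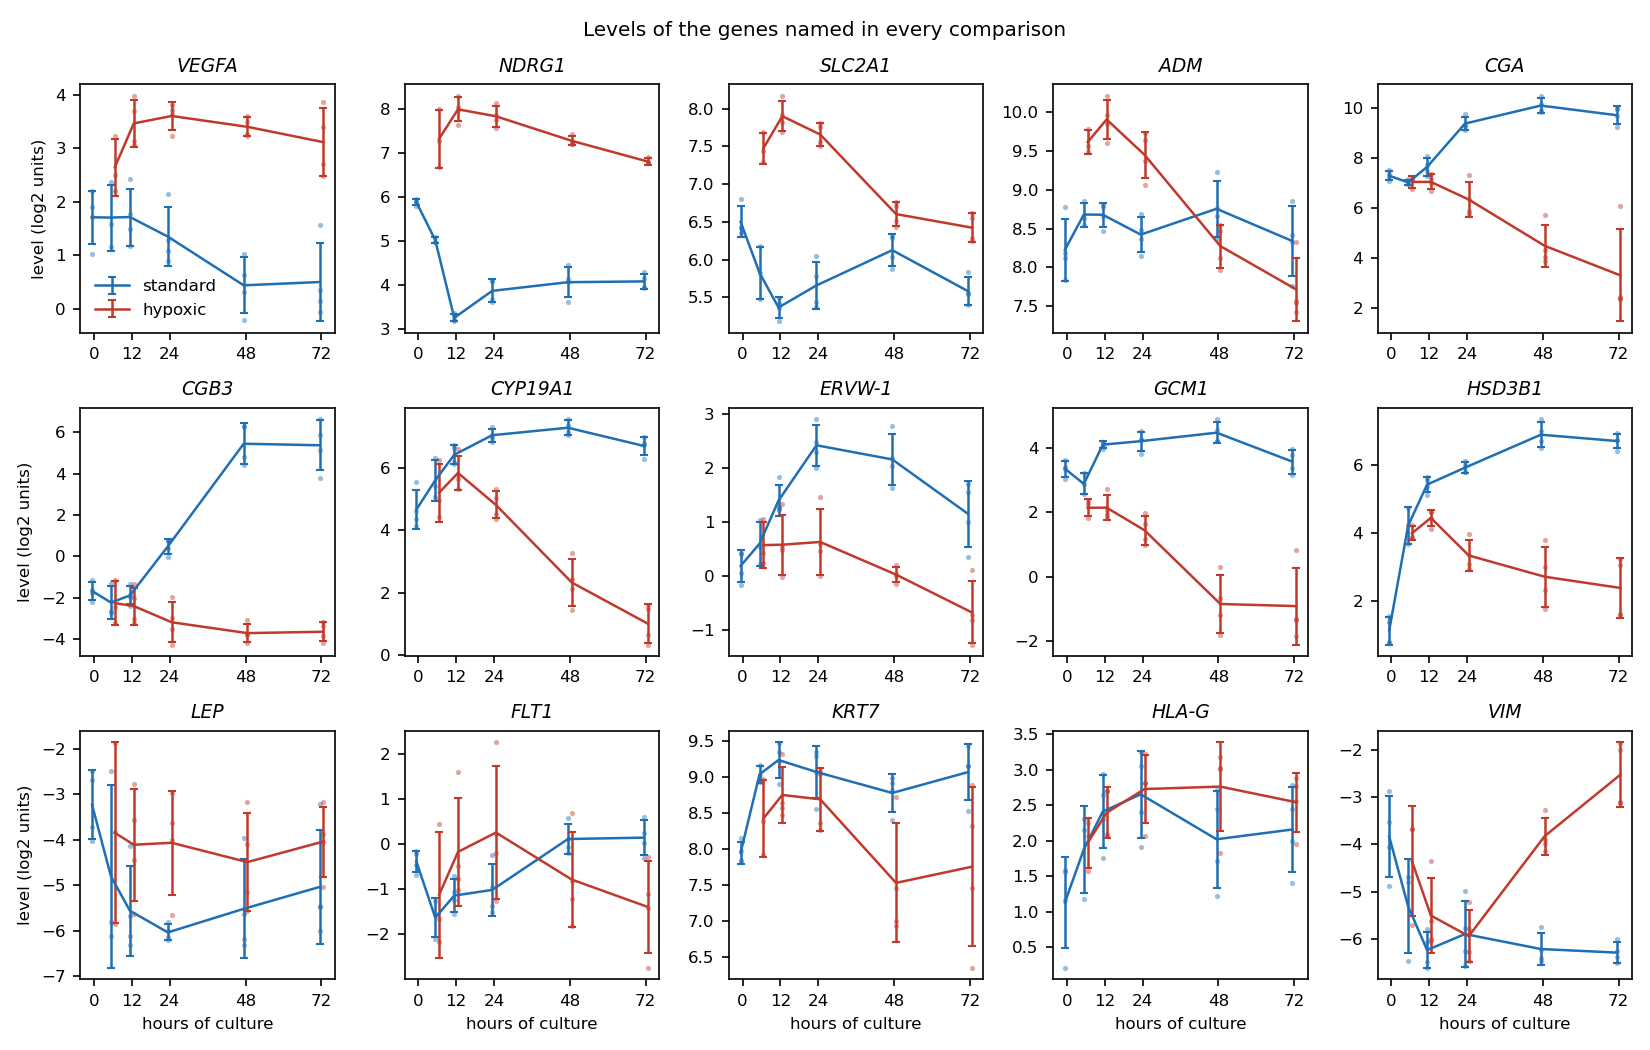
Log2 level of 15 genes named in advance (vertical axis, relative to the 75th percentile of each array) against hours of culture, with a point per placenta, lines through group means and bars of 1 SD, standard culture in blue and hypoxia in red. CGB3 lay 9.02 lower under hypoxia at 72 h and NDRG1 2.72 higher.

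The time course at standard oxygen addressed how trophoblasts change after plating. By 6 h (n = 3 placentas against 4 at 0 h) immediate early and heat shock transcripts had dropped. Of the interferon response genes 18 of 20 had risen (adjusted p = 0.2 with an estimated correlation). The test called 6910 genes, 3889 higher and 3021 lower, 6810 with the same sign in every placenta and 4128 of at least 2-fold. Without placenta 4 the count was 4352. On the 3 slides holding both times, 99.2% to 99.9% of them had the pooled sign. Immediate early genes had 18 of 22 lower, 20 adjusted over the list alone, at a median of -2.86 (adjusted p = 3.5e-17, and adjusted p = 0.033 with an estimated correlation), with FOS at -3.54 ± 0.24 and EGR2 at least 29.1-fold lower. Heat shock genes had 13 of 16 lower at a median of -1.76 (adjusted p = 8.5e-13, and adjusted p = 0.032 with an estimated correlation), with DNAJB1 at -2.61 ± 0.15. HIF targets had 15 of 32 lower and 1 higher (DDIT4, 1.46), 16 and 1 adjusted over the list alone, at a median of -0.52 (adjusted p = 0.00039). ANKRD37 fell by 3.28, NDRG1 by 0.86 and SLC2A1 by 0.68 (adjusted p = 0.0021, 0.14 without placenta 1).

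Interferon response genes had 18 of 20 higher and none lower at 6 h, at a median of 2.92 (adjusted p = 2e-12, adjusted p = 0.2 with an estimated correlation) and 2.94 to 3.16 within slides. IFI44L was at least 129-fold higher, MX1 rose by 5.69 ± 0.67 and STAT1 by 3.38 ± 0.33, each in 3 of 3 placentas. The other largest rises were CYP1A1 (7.52, 1 of 4 arrays at 0 h), CYP1B1 (6.90, 2 of 4) and MX2 (6.44, 1 of 4), and the largest falls were EGR2, ELF5 (at least 37.5-fold), SP5 (-4.57, 1 of 3 arrays at 6 h) and NR4A3 (-4.49). With normexp correction IFI44L rose by 4.14, CYP1A1 by 4.48 and MX2 by 3.65, while EGR2 fell by 2.31, ELF5 by 2.05 and SP5 by 2.46. List medians that it moved by over 1.5 times were those of immediate early (-1.80), amino acid response (0.57), inflammatory (-0.74), oxidative phosphorylation (-0.14) and extravillous genes (0.45). Amino acid response genes had 9 of 19 higher and 1 lower (ATF3, -1.49), 9 and 3 adjusted over the list alone, at a median of 1.17 (adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation), with PSAT1 at 3.55 and ASNS at 3.11. Inflammatory genes had 8 of 16 lower and none higher, 9 and 1 adjusted over the list alone, at -1.73 (adjusted p = 0.00091, adjusted p = 0.37 with an estimated correlation). Cholesterol genes had 8 lower at a median of -0.47 (adjusted p = 0.00091, adjusted p = 0.55 with an estimated correlation). Oxidative phosphorylation genes had 16 lower and 3 higher (NDUFS2, NDUFS3, SDHB), 17 and 3 adjusted over the list alone, at -0.22 (adjusted p = 0.0083, adjusted p = 0.55 with an estimated correlation, and 0.83 with normexp correction). Extravillous genes had 4 of 19 higher (CCR1, FN1, ITGA5, PLAC8) at 0.67 (adjusted p = 0.041, adjusted p = 0.54 with an estimated correlation, and 0.05 without placenta 5). Syncytiotrophoblast genes were not called as a list (median 0.19, adjusted p = 0.54), with ALPP, HSD3B1 (3.09) and PGF higher and HOPX lower. KRT7 rose by 1.09 (adjusted p = 0.028, with 0.094, 0.066 and 0.15 without placenta 1, 2 or 4). VIM was called lower in 2 of 3 placentas (adjusted p = 0.028) with 1 of 4 arrays at 0 h and no array at 6 h above background, and had 0.082, 0.28 and 0.076 without placenta 1, 4 or 5. With placenta as a block FLT1 (-1.25, adjusted p = 0.14) had 0.031, CYP19A1 (0.95, 0.064) had 0.019 and HLA-G (0.75, 0.17) had 7.4e-05. FLT1 had 0.049 without placenta 1, LEP (adjusted p = 0.18) 0.042 without placenta 2 and CYP19A1 0.015 without placenta 5, while CYP19A1 differed by 0.40 without placenta 1 (0.49).

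By 24 h of standard culture (n = 4 placentas per time) 21 of 34 syncytiotrophoblast genes had risen (adjusted p = 0.2 with an estimated correlation). Of the cell cycle genes 28 of 32 had fallen (adjusted p = 0.19 with an estimated correlation). The test called 9705 genes, 5103 higher and 4602 lower, 9399 with the same sign in every placenta and 6051 of at least 2-fold. On the 2 slides holding both times of the same placenta, 98.9% to 99.6% of them had the pooled sign. Syncytiotrophoblast genes had 21 of 34 higher and 2 lower (LEP, above background on 2 of 4 arrays at 0 h and none at 24 h, and OVOL1, -0.80), 22 and 3 adjusted over the list alone, at a median of 2.19 (adjusted p = 3.9e-07, adjusted p = 0.2 with an estimated correlation). HSD3B1 rose by 4.79 ± 0.33, PSG2 by 4.89, CYP19A1 by 2.39, ERVW-1 by 2.24, CGB3 by 2.16 and CGA by 2.09. GCM1 (0.86, adjusted p = 0.06) passed with placenta as a block (0.046) and without placenta 1 (0.0045). Cell cycle genes had 28 of 32 lower and none higher, 29 adjusted over the list alone, at a median of -1.37 (adjusted p = 2.4e-11, adjusted p = 0.19 with an estimated correlation), with CDC20 at -3.04. Immediate early genes had 20 of 22 lower, 21 adjusted over the list alone, at -3.83 (adjusted p = 7.8e-18), or -3.46 with dim genes at their bounds. Heat shock genes had 14 of 16 lower and 1 higher (HSPB1, 1.44), 15 and 1 adjusted over the list alone, at -1.82 (adjusted p = 6.4e-11).

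Interferon genes at 24 h still had 16 of 20 higher and 1 lower (OASL, -1.98), 17 and 1 adjusted over the list alone, at 2.25 (adjusted p = 2.2e-06, adjusted p = 0.35 with an estimated correlation). Inflammatory genes had 10 of 16 lower and 1 higher (CXCL5, 0.86), 10 and 2 adjusted over the list alone, at -1.77 (adjusted p = 0.00091, adjusted p = 0.3 with an estimated correlation). Cytotrophoblast genes had 13 of 24 lower and 5 higher (DLX3, EGFR, GATA3, ITGB4, SPINT1), 13 and 6 adjusted over the list alone, at -0.76 (adjusted p = 0.016, adjusted p = 0.35 with an estimated correlation), with SLC27A2 at -3.59. Cholesterol genes had 13 of 24 higher and 1 lower (DHCR24, -1.26) at 0.70 (adjusted p = 0.016, adjusted p = 0.53 with an estimated correlation). HIF targets had 12 lower and 2 higher (MXI1 and SERPINE1) at -0.34 (adjusted p = 0.0029, adjusted p = 0.11 with an estimated correlation). Glycolysis genes had 10 lower and 2 higher (PFKP and SLC16A3) at -0.41 (adjusted p = 0.016, adjusted p = 0.3 with an estimated correlation, and 0.059 with the mean over probes). The largest rises were IFI44L (at least 69.6-fold), SAA2 (at least 72.7-fold), XAF1 (at least 56.9-fold) and CBS (6.16, 3 of 4 arrays at 0 h above background). The largest falls were KRTAP3-1 (-7.79), EMP1 (-7.59, 3 of 4 arrays at 24 h), HBEGF (at least 89.2-fold) and CD83 (-7.32, 2 of 4). With normexp correction IFI44L rose by 3.21, SAA2 by 3.25 and XAF1 by 2.98, while HBEGF fell by 3.52 and CD83 by 4.70. List medians that it moved by over 1.5 times were those of immediate early (-2.31), interferon (1.42), inflammatory (-0.57) and glycolysis genes (-0.24). KRT7 rose by 1.12 (adjusted p = 0.0098, 0.09 without placenta 4), and VIM was called lower with 1 of 4 arrays at 0 h and none at 24 h above background (adjusted p = 0.0006, 0.34 with normexp correction).

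By 72 h of standard culture (n = 4 placentas per time) pregnancy-specific glycoproteins and chorionic gonadotropin were among the largest rises, and the whole cell cycle list had fallen. The test called 10394 genes, 5336 higher and 5058 lower, 10012 with the same sign in every placenta and 6640 of at least 2-fold. No slide holds first cultures of both times from the same placenta. On the slide that holds the 72 h array of placenta 1 and its second culture at 0 h, 94.6% of the called genes had the pooled sign, and on 2 slides with arrays of different placentas 99.2% and 99.0%. Cell cycle genes had 32 of 32 lower at a median of -3.55 (adjusted p = 1.4e-28, and adjusted p = 0.026 with an estimated correlation), with TYMS at -3.93 ± 0.26 and CDC20 at -4.37. Immediate early genes had 22 of 22 lower at -3.04 (adjusted p = 1.5e-15, adjusted p = 0.057 with an estimated correlation). Syncytiotrophoblast genes had 23 of 34 higher and 3 lower (CGB2, -1.21, ERVFRD-1, -3.61, and OVOL1, -1.47), 23 and 4 adjusted over the list alone, at 2.40 (adjusted p = 1.2e-08, adjusted p = 0.15 with an estimated correlation). CGB3 rose by 7.05 ± 0.52 (adjusted p = 2e-13), PSG2 by 6.92, PSG5 by 6.52, PSG1 by 6.51, PSG8 by 6.34, PSG3 by 6.26 and HSD3B1 by 5.58. CGA rose by 2.43, CYP19A1 by 2.05 and ERVW-1 by 0.96 (adjusted p = 0.011, 0.15 without placenta 4). The other largest rises were CBS (7.08, 3 of 4 arrays at 0 h), ALOX5 (at least 77.1-fold), TREML2 (at least 68-fold) and FAM78A (at least 88.9-fold). With normexp correction ALOX5 rose by 3.22, TREML2 by 3.05 and FAM78A by 3.64.

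The largest falls at 72 h were those of KRTAP1-5 (at least 676-fold), EMP1 (at least 523-fold), ADRB2 (at least 220-fold), NRARP (at least 141-fold), KRTAP2-3 (at least 118-fold) and HBEGF (at least 110-fold). KRTAP3-1 (-11.10, 2 of 4 arrays at 72 h), SFN (-7.59), RRAD (-7.38, 1 of 4) and TENT5C (-7.18, 3 of 4) completed them, each in 4 of 4 placentas. With normexp correction these falls were smaller, among them KRTAP1-5 at -6.17, EMP1 at -5.57, ADRB2 at -4.70, NRARP at -3.73, KRTAP2-3 at -3.80, HBEGF at -3.66 and RRAD at -4.56. The median of the cell cycle list was -2.00 and that of the inflammatory list -0.55 with that correction. Cytotrophoblast genes had 14 of 24 lower and 3 higher (EGFR, ITGB4, TEAD4), 14 and 4 adjusted over the list alone, at -0.69 (adjusted p = 9.5e-05, adjusted p = 0.15 with an estimated correlation). Extravillous genes had 10 of 19 higher and 2 lower (MMP9, MYCN), 11 and 2 adjusted over the list alone, at 1.10 (adjusted p = 0.0034, adjusted p = 0.24 with an estimated correlation), with FN1 at 4.02. Heat shock genes had 12 of 16 lower and 1 higher (HSPB1, 1.39) at -1.56 (adjusted p = 9.5e-05, adjusted p = 0.24 with an estimated correlation). Inflammatory genes had 10 of 16 lower and 1 higher (CXCL5, 0.83) at -1.93 (adjusted p = 0.0025, adjusted p = 0.29 with an estimated correlation). Interferon genes were no longer called as a list (median -0.39, adjusted p = 0.68). VEGFA fell by 1.21 (adjusted p = 0.0045, 0.062 without placenta 1 and 0.057 without placenta 4). HLA-G rose by 1.03 (adjusted p = 0.022, 0.075 without placenta 2 and 0.11 without placenta 5). KRT7 rose by 1.12 (adjusted p = 0.0093, 0.067 without placenta 4), and VIM was called lower with 1 of 4 arrays at 0 h and none at 72 h above background (adjusted p = 6.3e-05, 0.13 with normexp correction). LEP (-1.80, adjusted p = 0.061) passed with placenta as a block (0.019) and without placenta 1 (0.031).

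**Figure D3:**
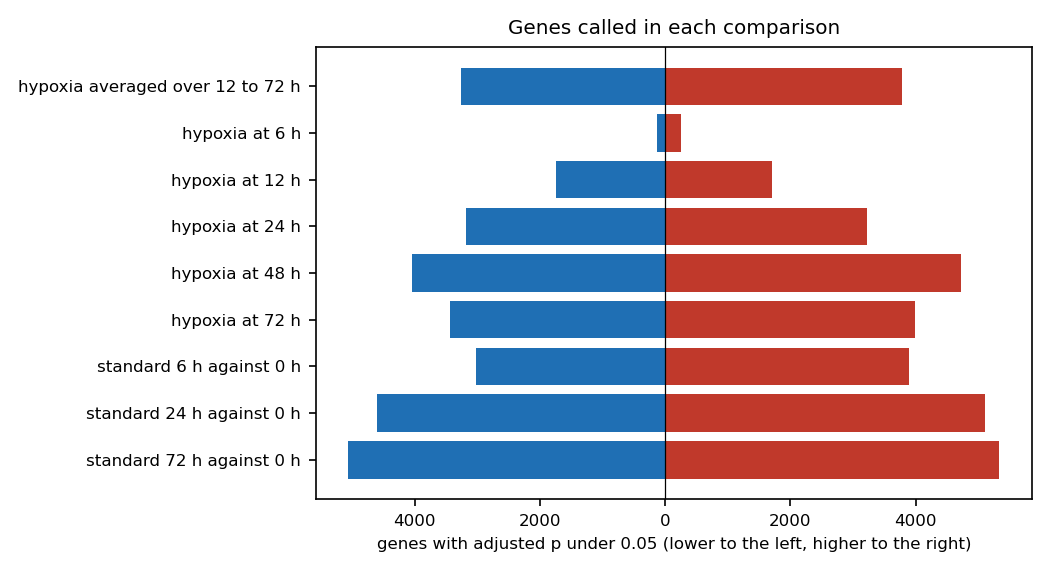
Number of genes called in 9 comparisons (horizontal axis), lower to the left in blue and higher to the right in red. The bars grow from 373 genes at 6 h of hypoxia to 10394 over 72 h of standard culture.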

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

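The tests of TEK and FGD5, of macrophages and of the shrinking HIF response were chosen after the result was seen, and the test of slides for the interferon genes before. A difference between times in the effect of hypoxia, tested as an interaction from 12 to 72 h, was found for 4652 genes. Among the genes named in advance or by the smallest p, hormone and placental genes had adjusted p-values of 1.68e-11 for LHB, 7.41e-11 for CGB3, 4.91e-10 for INSL4, 4.75e-09 for CYP19A1, 1.15e-07 for CGA, 2.35e-06 for HSD3B1 and 2.05e-05 for GCM1. All 7 lay lower under hypoxia at 72 h than at 12 h. TBX3 had an adjusted p of 4.1e-12, PGRMC2 of 9.35e-11 and SPIRE2 of 4.48e-10. The HIF targets SLC2A1, NDRG1 and ADM had 1.77e-08, 1.48e-06 and 6.24e-06. VIM had 0.000248 and FLT1 0.0202, and both of these calls were lost under an alternative (VIM at 0.2 with normexp correction, FLT1 at 0.17 without placenta 2). In 46 sets of 4 or more arrays checked for a sample far from the others, 0 were found and chance would give about 2.3.

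TEK, the angiopoietin receptor, and FGD5, both known from endothelium, rose by a log2 difference of 5.71 and by at least 28.3-fold under averaged hypoxia. More endothelial cells under hypoxia would bring their other transcripts, but the other 4 measured genes of the endothelium list had a median of -0.85 (SD 1.08), with 0.40 as the highest. CDH5, the most abundant of them, went from a mean level of 1.5 in standard culture to -0.28, and VWF from -2.97 to -2.57. Of the 5 genes of the list 4 were above background on most arrays, and 0 were in another list. The panel is small: PLVAP was above background on 5 of 42 arrays, and CDH5 had itself risen from -0.12 at 0 h in standard culture. The cells were purified on Percoll, but how many endothelial cells remained was not measured. Scaling of the arrays as the whole cause is argued against, since the lowest difference of either gene under the other scalings was 2.29. Induction by hypoxia in the trophoblasts is a candidate explanation, as a hypothesis found and tested on the same data.

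Interferon response genes rose by a median of 2.92 (SD 1.84) within 6 h of standard culture, though as a list they had an adjusted p = 0.2 with an estimated correlation. A growing share of macrophages would raise their own genes alike. The macrophage list, however, had a median of 0.0632 (SD 0.85) over 11 genes, 9 of them above background on most arrays and 0 in another list. Its most abundant genes parted, CSF1R moving from a mean level of 3.23 to 5.17 and CD14 from 0.56 to -1.04, and Percoll purification would remove such cells. Slides as the cause are argued against, since the lowest within-slide median of the interferon list was 2.94. A response of the trophoblasts to isolation and plating may explain the rise, and no test separated it from a response of any remaining macrophages.

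Part of the HIF response may shrink from 12 to 72 h: of 26 HIF targets called higher at 12 h, 17 differed less at 72 h and 9 more, with a median shrinkage of 0.62 (SD 1.01). Scaling of the arrays stays open as a cause, since the lowest median under the other scalings was 0.27 (SD 1.04, 13 of 26 differing less) after quantile normalization, within its spread of 0. Of the 26, 10 were called in the interaction and differed less at 72 h, but they were chosen for that course, and BHLHE40 and HILPDA lost the interaction call after quantile normalization (adjusted p = 0.2 and 0.051) and in the authors' table (0.17 and 0.13). Rising levels in standard culture make up 34.9% of the median shrinkage of these 10, or 30.1% with ANGPTL4, which was not called at 12 h and lay lower at 72 h, a share between the bounds set for the test. The 10 changed by a median of 0.51 in standard and -1.30 in hypoxic culture, so both enter their shrinkage. A change in oxygen reaching the cells was not measured.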

How the results depend on the processing

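Normexp on median signals and the fit without the 6 h arrays of placenta 2 were chosen after the result was seen. All others were planned before the data were examined. Across all alternatives the 76 called list tests kept direction and side of the threshold in 1136 cases. They lost the call in 97, and 0 reversed. Uncalled list tests gained a call in 69 cases, 0 in the other direction. Named genes kept their side in 3611 cases, lost the call in 77 and gained it in 53. Interaction aside, 0 calls reversed. Where a count or value moved, the cause was not tested unless fewer samples or a stricter rule entered by construction. With normexp correction averaged hypoxia called 4598 genes and 6 h 234. It made 62 of 173 called differences of named genes and 13 of 76 list medians smaller by over 1.5 times, and turned 0. That correction also moved the median of all genes from 0.07 to 0.14 at 6 h, 0.01 to 0.19 at 12 h, 0.03 to -0.12 at 24 h and 0.06 to -0.17 over the first 6 h of standard culture. With placenta as a block 6 h called 936, 12 h 5284 and the interaction 7602, while the other counts stayed within 1.5 times and no call changed beyond those named beside their results. With slide as a block averaged hypoxia called 13092, 6 h 986 and the interaction 7487. Another choice of samples gave averaged hypoxia 11670 and 6 h 63. Both averaged counts took arrays, not placentas, as replicates. Without the 6 h arrays of placenta 2, 6 h called 137. The 2-fold rule left 3335 genes for averaged hypoxia, 1743 at 12 h, 3619 at 24 h, 5453 at 48 h, 4414 at 72 h, and 4128, 6051 and 6640 after 6, 24 and 72 h of standard culture. Leaving out 1 placenta gave 3944 to 6360 genes for averaged hypoxia, 96 to 428 at 6 h, 1849 to 3460 at 12 h, 4352 to 6528 over the first 6 h of standard culture and 2047 to 4125 for the interaction. Of 76 calls of gene lists 22 held with the estimated correlation. For 8% oxygen, HIF targets at 24 h went from 0.10 to -0.0903 after quantile normalization and to -0.0891 in the authors' table, and at 72 h from 0.59 to 0.39 (normexp), 0.16 (quantile) and 0.0731 (authors' table). Syncytiotrophoblast genes at 24 h went from -0.41 to -0.20, -0.58 and -0.64 in that order, and at 72 h from -0.90 to -1.84 (quantile) and -1.76 (authors' table). Normexp on mean signals was not run because the files lack that column, and the 2-fold rule has no meaning for tests of gene lists. Signal over background limits genes that are dim in a whole group, for which bounds are given in place of folds.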

Other observations

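The test of whether hypoxia holds back the changes of standard culture and the counts over other splits of the samples were chosen before their results were seen, except the splits of the interaction that part all pairs. At 8% oxygen there was 1 array at 24 h and 1, the dimmest of all 47, at 72 h, so no test. The HIF response seen under hypoxia was small at 8%. HIF targets had a median difference from standard culture of 0.10 at 24 h (-0.0903 after quantile normalization) and 0.59 at 72 h (0.16 after quantile normalization and 0.0731 in the authors' table), against 2.19 and 2.18 in the second hypoxic cultures of the same placenta. The median of all genes was itself 0.14 and 0.35. Percentiles among 10000 random lists of genes with matched levels were 24.2 and 66.8 for HIF targets. They rank genes within arrays and leave out differences between cultures: of 22 lists 6 lay at percentile 0 between the first and second hypoxic cultures at 24 h, and 0 at 72 h. HIF targets lay at -2.13 and -1.67 from the second hypoxic cultures and glycolysis genes at -2.47 and -2.14, where those cultures differed from the first by -0.25 and 0.10, and by 0.08 and 0.12. NDRG1 differed by 0.37 and -0.16, and VEGFA by -0.63 and 0.28. Syncytiotrophoblast genes lay lower, at -0.41 (-0.20 to -0.64 under the other scalings) and -0.90 (-0.94 to -1.84), percentile 0 at both times, against -1.74 and -4.49 in the second hypoxic cultures, which differed from the first by 0.11 and -0.12. CGB3 differed by -3.58 and -4.52, CYP19A1 by -0.92 and -1.58, CGA by -0.39 and -0.50, and GCM1 by 1.02 and 1.11. Cholesterol synthesis genes lay higher, at 0.84 and 1.01, and the second hypoxic cultures differed from the first by -0.90 and 0.55 for them. Across genes, which are not independent replicates, the 8% difference correlated with the hypoxia difference of the other placentas at 0.11 and 0.13, against 0.62 and 0.64 for the second hypoxic cultures.

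Interferon genes differed between cultures of placenta 1 at 24 h. Their median difference from the standard first culture was -3.70 at 24 h and -2.58 at 72 h in the second hypoxic cultures, and 0.71 and -2.02 in the first. At 8% oxygen it was -4.11 and -1.72. The labels number the 8% arrays as first replicates and give no second standard culture at 24 or 72 h. Culture and oxygen cannot be told apart in any 8% difference from standard culture. Over all genes, the 3 pairs of first and second cultures differed with an SD between 0.77 and 0.88 (log2), and 69 pairs of different placentas in the same group with a median of 0.80.

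The genes that change over 72 h of standard culture tended to differ the other way under hypoxia at 72 h, and hypoxia may hold back the changes of standard culture. With the change taken from 2 placentas and the hypoxia difference from the other 2, the weaker correlation across genes was -0.27 and the other -0.31 (Spearman's rho -0.20 and -0.25). The weaker value lies between the bounds set in advance, so the test leaves the hypothesis open. The slope of the change under hypoxia was 74.5% and 72.4% of that in standard culture.

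Other splits of the same samples were used to ask whether chance can give as large a count. Over all 35 splits the real one was the only 1 to call as many genes for averaged hypoxia, with 7026 against 17 for the highest other. The same held at 12 h (3438 against 24), 24 h (6398 against 516), 48 h (8753 against 2713) and 72 h (7420 against 1707). These shares lie under 0.05, but most of the splits ignore the pairs. Only 8 of the 35 part every pair of cultures of a placenta, too few on their own for a share under 0.05, so chance cannot be excluded within the pairs. The others of these 8 gave at most 0, 0, 4, 1456 and 808 in that order. The highest others part 2 of the 4 pairs from 12 to 72 h and 0 of 4 for averaged hypoxia, so they put both cultures of a placenta on one side. For standard culture at 6, 24 and 72 h the real split was also the only 1 of 35 to call as many. The counts were 6910 against 3938, 9705 against 296 and 10394 against 1346, or against 3326, 4 and 211 among splits that part as many pairs. Here too only 8 splits do so, the real one included. For the interaction 100 drawn splits gave 4652 for the real one and 3946 for the highest other, but they ignore the pairs. Of 100 splits that part all 16 pairs, 10 called as many, the real one included, with 8445 as the highest other, so chance is left open for this count. The 9 others swapped at least 3 more pairs at one time than at another, which turns the hypoxia difference into a difference between times, and the splits that swapped more evenly called at most 1793. At 6 h of hypoxia the 10 splits are too few for a share under 0.05, with 373 for the real split and 251 for the highest other, which parts 1 of the 3 pairs.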
